A study of Mus musculus with 2 samples.

How the data were processed

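The series holds chromatin immunoprecipitation sequencing of CHOP in mouse liver after tunicamycin, with 1 immunoprecipitated library from a pool of 3 mice and 1 input library. The peak list of the immunoprecipitate was analysed. A processed file of the input was not used here. Per the labels' protocols, the antibody was a mouse monoclonal against CHOP tested beforehand at the Ppp1r15a promoter, sequencing was single-end, reads were aligned to mm10 with Bowtie allowing at most 2 mismatches, and reads stacked more than 2 deep at a position and strand were dropped. Per the labels' protocols and the submitters' processing notes, alignments were filtered with SAMtools 1.9 and Sambamba 0.7.1, peaks were called with MACS2 2.1.2 at default settings and annotated with ChIPseeker. The version of Bowtie is not given in the sources used here.

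For each peak the authors deposited a fold enrichment, which is a ratio of the pileup at the summit to the local background. The authors also deposited −log10 p and −log10 q of the same comparison, a score, and the offset of the summit from the peak start. The deposited score equals 10 times −log10 q within 1 in all 14157 peaks and was used only in an alternative. These values are the authors', and they were used to describe, rank or filter peaks within the list.

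MACS2 computes fold as (pileup + 1)/(background + 1) and p from a Poisson distribution, so the whole-number pileup and the background can be solved from fold and −log10 p. This gave a solution for all 14157 peaks, with a largest residual of 3.13e-05 in −log10 p against a tolerance of 0.0001. The pileup had a median of 11 reads (4 to 329). In 4181 peaks (29.5%) the background was within 0.001 of the genome-wide value of 0.333 reads, so a single read at the summit moves the fold of such peaks by much. Exact Poisson intervals at 95% on the pileup were carried to the fold with the background held fixed. The summit is the highest point of its peak, reads are without molecular identifiers, and the intervals cover counting error only. Total library depth is not stated in the sources used here.

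Coordinates are mm10, and the GRCm38.p6 sequence with GENCODE M21 gene models was used, whose chromosome lengths fit the peaks. Start sites were those of protein-coding transcripts of protein-coding genes. A promoter peak has its summit within 1 kb of a start site, a distal peak has not, and a peak counts for every gene within that distance. Of 21866 protein-coding genes, 6100 (27.9%) had a promoter peak. The share of summits per annotated class and per chromosome was set against the share of non-N bases (exact binomial test). The annotation holds a second gene under the name Ddit3, and the gene at chromosome 10, 127290774 to 127296288, was used.

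A set of 33 gene lists with 668 members, of which 666 matched a gene, and 27 consensus motifs were fixed before the data were examined, as were the tests and the first alternatives. Lists were tested with Fisher's exact test against all other protein-coding genes on chromosomes that hold peaks, and again by logistic regression with the GC share and CpG observed/expected ratio within 500 bp of the start sites as covariates (likelihood-ratio test). Odds ratios of the Fisher tests were computed with 0.5 added to each count. Motif matches on either strand within 50 bp of the summit were compared with a 101 bp window 500 bp away on a random side (exact McNemar test). Differences in mean log2 fold were tested with 100000 permutations. All tests are two-sided unless stated, and adjusted p-values are Benjamini-Hochberg within each family at a threshold of 0.05. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Biopython 1.88 and matplotlib 3.10.9 was used.

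Genes named in the text follow a rule fixed in advance: always Ppp1r15a, Ddit3, Trib3, Atf3, Atf4, Chac1, Ero1l (also called Ero1a), Asns, Herpud1, Hspa5, Cebpa, Cebpb, Hnf4a, Ppara, Fgf21, Gdf15, Nupr1 and Alb, then the 10 genes with the highest promoter fold, up to 4 members per list with the highest promoter fold, and the genes nearest the 5 distal peaks of highest fold. Other names are said to be chosen afterwards. For a gene with several promoter peaks the fold given is the highest.

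After the distal peaks were seen, each summit window and its control window were aligned to a primate SINE (Alu) consensus and to its rodent counterpart (B1), both written from general knowledge and not taken from a repeat database, and a window matched the primate repeat if its local score was at least 26 and exceeded the rodent score by at least 3. Windows with 5 or more units of a pentamer found in primate satellite DNA were added in the alternative that removes such peaks. Alternatives tried were stricter peak thresholds, the peaks at or above the median fold, removal of the top 1% by score with repeat-masked peaks, other promoter distances and start-site sets, nearest-gene assignment, other motif windows and controls, −log10 q in place of fold, and removal of the compact and of the repeat-matching peaks. Single motifs were followed through the alternatives only where they had passed the test first, a limit set after all motifs had been followed in a first pass, in which most changes of direction were of motifs that had not passed.

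The steps were tested on simulated data. Reads were recovered for 1000 of 1000 simulated peaks. Of 200 raised lists, Fisher's test called 198 and the logistic model 197, with 2 and 3 calls among 460 unchanged lists. The simulated lists were random draws of genes, so these rates do not cover lists whose promoters are rich or poor in CpG. A planted composite element was called in 5 of 5 runs with 2 calls among 120 unplanted motifs (leaving out motifs that the planted element completes with its neighbouring bases), and the permutation test called 10 of 10 shifted sets and 0 of 20 unshifted ones. Summit and control windows of the motif runs were random sequence of equal base frequencies, so a difference in base composition between them was not simulated. There was no replicate to leave out, and reads, RNA and other antibodies were not analysed here.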

Results

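Binding of CHOP (the product of Ddit3), a C/EBP-family transcription factor made when protein folding in the endoplasmic reticulum is disturbed, was mapped by chromatin immunoprecipitation and sequencing in the liver of wild-type mice given tunicamycin, an inhibitor of N-linked glycosylation, at 1 mg/kg for 8 h. Chromatin of 3 mice was pooled into 1 immunoprecipitated library, and 1 input library was the control for peak calling. The immunoprecipitate is represented by the authors' list of 14157 peaks, and the input enters only through the local background of each peak. There was no replicate and no untreated or CHOP-deficient sample, so every test below runs across peaks or genes of this list and says nothing about variation between animals. The question addressed is at which mouse genes and sequences CHOP peaks lay in the stressed liver.

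The peaks ranged in width from 172 to 6535 bp, with a median of 285 bp. The authors' fold enrichment over the local background had a median of 6.75 and ran from 2.31 to 158.2. The median peak rested on 11 reads at its summit, and 6489 peaks (45.8%) rested on 10 or fewer. The counting error of a typical peak is therefore wide: a promoter peak of Gdf15 with 8 reads had a fold of 6.75 with a 95% exact Poisson interval of 3.34 to 12.6, whereas the peak of Cebpg with 329 reads had a fold of 131 with an interval of 117 to 146. Intervals given for folds cover counting error at the summit only.

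CHOP peaks were over-represented at gene starts. Of the 14157 summits, 6306 (44.5%, 95% Wilson interval 43.7 to 45.4%) were within 1 kb of the start site of a protein-coding gene, a zone that holds 2.44% of the genome, which is an 18.3-fold excess (exact binomial test, two-sided, −log10 p = 6032). Promoter summits lay a median of 108 bp from the nearest start site, and 3030 of them (48.0%) lay within 100 bp. Downstream or at the start site were 3964 (62.9%). Outside promoters, coding exons held 232 summits (1.64%, 1.49-fold over their share of the genome, exact binomial test, adjusted p = 1.43e-08) and 5′ UTRs held 17 (3.15-fold, adjusted p = 6.00e-05). Introns with 3529 summits (24.9%, 0.726-fold) and intergenic sequence with 3934 (27.8%, 0.456-fold) held fewer than their length predicts, as did 3′ UTRs with 139 (0.826-fold, adjusted p = 0.0221; exact binomial tests with Benjamini-Hochberg adjustment over the 6 classes). The excess in coding exons was no longer past the threshold among the peaks of higher fold (exact binomial test, adjusted p = 0.107), nor was the deficit in 3′ UTRs (adjusted p = 0.413).

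By chromosome, the gene-rich chromosomes 11 and 19 carried 1.62 and 1.53 times the number of peaks their length predicts (1030 and 475 peaks; adjusted p = 1.42e-48 and 1.56e-17, exact binomial tests), but 1.05 and 0.994 times the number predicted from their start sites (adjusted p = 0.168 and 0.970). Chromosome X carried 355 peaks, 0.406 times the number predicted from its length and 0.686 times that predicted from its start sites (exact binomial tests, adjusted p = 8.78e-92 and 1.25e-13). Chromosome Y carried 17. In all, 15 of 22 chromosomes departed from the length-based expectation and 13 from that based on start sites, the latter including chromosome 7 at 0.622 times (exact binomial test, adjusted p = 6.63e-53) and chromosome 12 at 1.36 times.

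The strongest promoter peaks were led by genes of the integrated stress response. Cebpg, which encodes a C/EBP partner of ATF4, had the highest fold of any promoter (131, chromosome 7, 35055568 to 35056776, summit at -232 bp from the start site, with a C/EBP-ATF composite element within 50 bp of the summit). Trib3, a pseudokinase induced by ATF4 and CHOP, followed at 106-fold (interval 90.0 to 123; chromosome 2, 152343635 to 152344428). Ssu72, a phosphatase of the RNA polymerase II tail, reached 94.2-fold and Fem1c, a substrate receptor of a ubiquitin ligase, 90.9-fold. A peak shared by Lyrm1 and Dcun1d3 on chromosome 7 reached 88.3-fold (75.6 to 103), and a peak between Mttp, the microsomal triglyceride transfer protein that loads lipid onto apolipoprotein B, and Trmt10a, a tRNA methyltransferase, reached 83.8-fold (69.4 to 100), with its summit at -433 bp from the start site of Mttp and 22 bp inside Trmt10a. Wfs1, an endoplasmic reticulum membrane protein lost in Wolfram syndrome, and Lmo4, a LIM-domain cofactor, had 79.4-fold and 79.1-fold peaks. Position alone cannot assign these shared peaks to either neighbour.

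Integrated stress response genes and known CHOP or ATF4 targets had promoter peaks far more often than other genes. Of 24 listed genes, 19 (79.2%, Wilson interval 59.5 to 90.8%) had a summit within 1 kb of a start site, against 27.8% of the other protein-coding genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 4.34e-06 over 33 lists). Because these genes were listed as known targets of CHOP or ATF4, their rate is not an unbiased sample of liver genes. Ddit3, which encodes CHOP itself, had a 60.9-fold peak (49.2 to 74.5) whose summit lay 267 bp upstream of its start site on chromosome 10, with composite, AP-1 and GC box matches. Vegfa, the vascular growth factor, had a 62.0-fold peak in its first kilobase. Ppp1r15a, which encodes the phosphatase subunit GADD34 that reverses eIF2α phosphorylation and is the locus the submitters used to test the antibody per the labels' protocols, had a 40.6-fold peak (31.2 to 51.9, 61 reads) on chromosome 7, 45525878 to 45526509, with its summit in the 5′ UTR 48 bp downstream of a start site.

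Other members had peaks of lower fold. Chac1, a glutathione-degrading enzyme, had a 29.9-fold peak, Ero1l, the oxidase that drives disulfide formation, 25.7-fold, and Atf3 23.8-fold. Asns, asparagine synthetase, stood at 10.6-fold on 23 reads, Nupr1 at 8.25-fold on 10 reads, Atf4 at 6.85-fold (3.95 to 11.2) on 14 reads and Gdf15, a stress-induced hormone, at 6.75-fold on 8 reads. At Cebpb the nearest summit was outside the 1 kb limit: a 76.3-fold peak (65.1 to 89.0, 161 reads) covered chromosome 2, 167688686 to 167690448, with its summit in the 3′ UTR, 1172 bp from the start site. The peak spanned the whole gene (167688915 to 167690418), its start site included, and only the place of the summit kept it from counting as a promoter peak. Fgf21, a hepatic hormone, had no promoter peak. The summit nearest to it, 8224 bp away in sequence annotated as intron, had a fold of 81.0 and belongs to a class of compact peaks 290 to 340 bp wide described with the distal peaks.

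Genes of endoplasmic reticulum folding and quality control also had promoter peaks at a high rate. Among chaperones and folding genes 15 of 19 had a promoter peak (adjusted p = 3.64e-05, Fisher's exact test), led by Hyou1, an ER HSP70-like chaperone, at 51.3-fold, Atf6, an ER stress sensor, at 30.1-fold, Calr, calreticulin, at 15.7-fold and Dnajb9 at 12.0-fold. Hspa5, the major ER chaperone BiP, had no summit within 1 kb, but a 26.2-fold peak (18.5 to 36.2, 35 reads) lay 1726 bp from its start site at chromosome 2, 34770081 to 34770497, in intergenic sequence. Among genes of ER-associated degradation and translocation 15 of 20 had a promoter peak (Fisher's exact test, adjusted p = 8.99e-05), including Sec61b at 16.9-fold, Erlec1 at 15.1-fold and Herpud1 at 14.4-fold (9.16 to 21.7). Promoter base composition accounted for part of both excesses: with GC share and CpG ratio as covariates in a logistic regression, the adjusted p was 0.0866 for chaperones and 0.125 for degradation genes.

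Genes of translation and amino acid supply formed another group with promoter peaks. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, had promoter peaks at 14 of 20 genes (adjusted p = 5.18e-04, Fisher's exact test; 0.00978 with base composition as covariate), led by Gars (74.9-fold, 65.6 to 85.1), Iars (32.2-fold), Sars (27.5-fold) and Eprs (22.2-fold). All 4 carried a composite element at the summit. Genes of serine, one-carbon and amino acid synthesis had promoter peaks at 14 of 17 (82.4%, Fisher's exact test, adjusted p = 3.64e-05; 1.15e-04 with composition), among them Aldh18a1 (46.9-fold), which makes the proline precursor, Mthfd1l (31.1-fold), Phgdh, the entry enzyme of serine synthesis (17.8-fold), and Got1 (16.5-fold). Translation initiation factors had 16 of 25 (Fisher's exact test, adjusted p = 7.38e-04), with Eif3c at 35.2-fold, Eif1 at 21.9-fold and Eif1a at 20.4-fold, but their rate was not past the threshold with composition as covariate (adjusted p = 0.360). Cytosolic ribosomal proteins had 12 of 26 (Fisher adjusted p = 0.0987).

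The list with the highest rate was the circadian clock, of which 18 of 20 genes had a promoter peak (90.0%, Wilson interval 69.9 to 97.2%, adjusted p = 3.50e-07, Fisher's exact test; 3.74e-04 with base composition). Nfil3, a bZIP repressor, had a 30.7-fold peak with a C/EBP palindrome at the summit, Per2 21.4-fold, Rora 19.2-fold and Cry1 17.6-fold. Autophagy genes had 16 of 20 (Fisher adjusted p = 2.10e-05; 0.00722 with composition), including Atg3 at 32.5-fold and Map1lc3a, which encodes an LC3 protein, at 19.8-fold with a CRE palindrome. NRF2 antioxidant genes had 13 of 20 (Fisher adjusted p = 0.00218; 0.0257 with composition), including Hmox1, heme oxygenase, at 11.6-fold, Nfe2l2 at 7.53-fold and Gsr at 7.35-fold. Among the peaks of higher fold alone, the adjusted p of both the autophagy and the NRF2 list was 0.303.

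Immediate early and AP-1 genes had promoter peaks at 14 of 23 (adjusted p = 0.00491, Fisher's exact test), led by Btg1 at 16.5-fold, Jund at 13.5-fold and Klf6 at 12.6-fold. Apoptosis regulators had 11 of 20 (Fisher adjusted p = 0.0262), with Diablo, an inhibitor of caspase inhibitors, at 28.4-fold, Bax at 15.1-fold and Mcl1 at 10.3-fold. With composition as covariate the adjusted p was 0.70 for the first and 0.60 for the second, and with summits within 500 bp the Fisher adjusted p was 0.0581 and 0.122. Inflammatory signalling genes had 9 of 20 (Fisher adjusted p = 0.205), with Nfkbia at 11.7-fold and Tnfaip3 at 11.4-fold. Cell cycle genes had 7 of 20 (Fisher adjusted p = 0.564), with Foxm1 at 21.2-fold, and oxidative phosphorylation genes 8 of 20 (adjusted p = 0.305), with Sdha at 15.7-fold.

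Among genes that define the hepatocyte, transcription factors had promoter peaks at 13 of 25 (adjusted p = 0.0269, Fisher's exact test; 0.0479 with composition). Prox1, a regulator of liver identity, had a 29.6-fold peak, Onecut1 19.3-fold and Rxra 16.9-fold. Cebpa had peaks in its coding exon, the stronger at 8.34-fold (5.25 to 12.7, 20 reads), and Ppara, the regulator of fatty acid oxidation, had a 6.26-fold peak (3.73 to 9.93) 25 bp upstream of a start site. Hnf4a had no promoter peak. The summit nearest to it, in an intron 7766 bp away, rested on 5 reads and had a fold of 4.50 (1.97 to 9.50). The call for this list was not past the threshold with −log10 q of at least 5 (Fisher adjusted p = 0.0549), with a fold of at least 5 (0.0651), among the peaks of higher fold (0.201), with the outermost start site only (0.0827) or without the peaks that match a primate repeat (0.0903).

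Apart from the amino acid synthesis list above, no list of metabolic or secretory liver genes passed Fisher's test for peaks within 1 kb. Fatty acid oxidation genes had promoter peaks at 7 of 20 (adjusted p = 0.564, Fisher's exact test), including Hadh, a mitochondrial dehydrogenase of β-oxidation, at 8.80-fold. Lipogenesis had 9 of 20 (Fisher adjusted p = 0.205), with Dgat1 at 19.4-fold and Lpin2 at 18.6-fold, and passed with summits within 3 kb (adjusted p = 1.81e-04). Cholesterol synthesis had 8 of 20 (Fisher adjusted p = 0.305), with Sc5d at 21.2-fold and Cyp51 at 14.2-fold. Gluconeogenesis and glycogen genes had 7 of 18 (Fisher adjusted p = 0.395), with Foxo1 at 24.7-fold and Pck1, which catalyses the committed step from oxaloacetate, at 10.5-fold. Urea cycle and amino acid catabolism had 6 of 21 (Fisher adjusted p = 1), with Ass1 at 9.0-fold. Lipoprotein assembly had 2 of 17 (Fisher adjusted p = 0.270), which were Mttp and Apoh, and cytochrome P450 and drug metabolism had 2 of 21 (adjusted p = 0.147), which were Cyp1a2 at 8.54-fold and Ugt1a1 at 7.12-fold. Below other genes, lipoprotein assembly passed with the nearest start site only (Fisher adjusted p = 0.0227) and P450 genes without top-score and repeat-masked peaks (0.0297). Counting any peak within 50 kb whose nearest gene it was, 18 of all 33 lists passed above other genes, so passing there was not particular to liver genes. Among the 18 were 6 further lists of metabolic or secretory liver genes: lipogenesis (Fisher adjusted p = 6.26e-05), bile acid (0.00641), acute-phase (0.00814), plasma protein (0.0175), gluconeogenesis (0.0202) and urea cycle genes (0.0341).

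In contrast to the Fisher test, the model with promoter composition placed 4 secretory or liver-specific lists above the rate their CpG-poor promoters predict. Secreted plasma proteins had 6 of 20 (odds ratio 9.95, likelihood-ratio test, n = 21866 genes, adjusted p = 0.00154), including Cp at 10.5-fold and Rbp4 at 7.74-fold. Complement and coagulation had 6 of 22 (odds ratio 8.5, n = 21866, adjusted p = 0.00154), including F2, prothrombin, at 10.5-fold. The 44.2-fold peak of Hc, complement C5, counts among the 6, is 314 bp wide, lies 939 bp inside the gene in an intron and has a summit that matches a primate repeat. Acute-phase proteins had 5 of 20 (odds ratio 6.52, n = 21866, adjusted p = 0.0303), with Il6ra at 19.0-fold and Lcn2 at 9.0-fold, and bile acid genes had 5 of 16 (odds ratio 5.88, adjusted p = 0.0479), with Acox2 at 24.7-fold and Amacr at 15.6-fold. Their adjusted p in Fisher's exact test ran from 0.887 to 1. Alb, serum albumin, had no promoter peak, and the summit nearest to its start site, 3796 bp away in an intron, had a fold of 15.0 (9.57 to 22.6).

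Genes of other cell types and tissues seldom had promoter peaks. No promoter peak was found at 18 Kupffer cell and macrophage markers (adjusted p = 0.0153, Fisher's exact test), at 20 neuronal and photoreceptor genes (adjusted p = 0.00609) or at 19 olfactory receptors (adjusted p = 0.00936), and the Wilson intervals for these shares reached 17.6%, 16.1% and 16.8%. The neuronal list remained below its prediction with base composition as covariate (likelihood-ratio test, n = 21866 genes, adjusted p = 0.00154), whereas the Kupffer (0.364) and olfactory (0.595) lists did not pass. Among the peaks of higher fold, where fewer genes have a peak, the Fisher adjusted p was 0.201, 0.175 and 0.201. Skeletal muscle genes had 2 of 22 (Fisher adjusted p = 0.109), Mylpf and Tnnt1, both with folds of 5.03 or less, and passed as lower with −log10 q of at least 5 (0.0264) or the nearest start site only (0.0479). With any peak within 50 kb the neuronal list did not pass (Fisher adjusted p = 0.0877). Endothelial and stellate markers had 2 of 20 (Fisher adjusted p = 0.147), Reln and Hand2, and cholangiocyte markers 2 of 13 (adjusted p = 0.632). Over all 33 lists, 12 had a higher and 3 a lower rate than other genes, and with base composition as covariate 11 were higher and 1 lower.

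**Figure D1:**
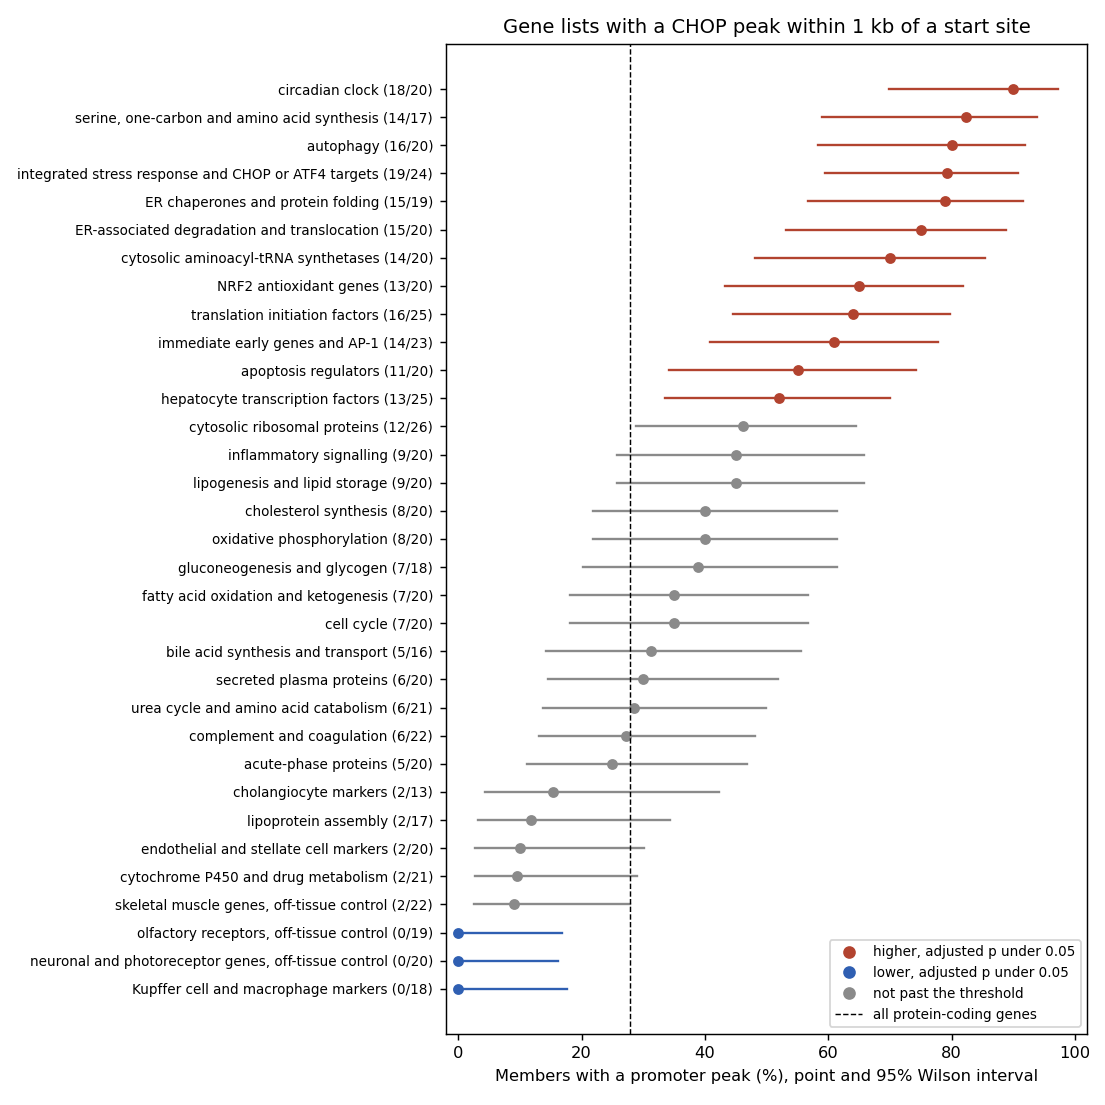
Share of each gene list with a CHOP peak summit within 1 kb of a start site, in percent, with 95% Wilson intervals and the number of members with a peak over the number tested. The dashed line marks all protein-coding genes (27.9%). Red points passed the Fisher test above it (12 lists), blue points below it (3 lists), and grey points did not pass.

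The C/EBP-ATF composite element (TGATGMAA, where M is A or C), bound by heterodimers of C/EBP proteins with ATF4 and its relatives, was the sequence most enriched at distal summits. It lay within 50 bp of 608 of 7851 distal summits (7.74%, Wilson interval 7.17 to 8.36%) against 0.853% of the control windows 500 bp away, a ratio of 9.01 (exact McNemar test, two-sided, Benjamini-Hochberg adjusted p = 2.32e-111 over 27 motifs). At promoter summits it was rarer, with 96 of 6306 (1.52%) against 0.507% of the control windows (ratio 2.97, exact McNemar test, adjusted p = 6.49e-08). The C/EBP palindrome was found at 2.03% of distal summits against 0.713% (exact McNemar test, adjusted p = 8.90e-12) and the AP-1 site at 2.98% against 1.63% (adjusted p = 9.29e-08). At promoter summits neither passed, with 44 against 35 for the palindrome (exact test, adjusted p = 0.523) and 54 against 72 for the AP-1 site (adjusted p = 0.211). The HNF4A site, of a nuclear receptor that defines hepatocytes, was at 25 distal summits against 9 control windows (ratio 2.68, exact test, adjusted p = 0.0305). With fewer peaks or another control the ratio stayed similar but did not pass: 2.47 with a fold of at least 5 (exact test, adjusted p = 0.0677), 3.18 among the peaks of higher fold (0.057) and 2.22 with the control window 1000 bp away (0.0707).

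Promoter summits were marked by general promoter elements and the E-box. The GC box of SP and KLF factors was at 8.63% of promoter summits against 2.84% of the control windows (adjusted p = 6.25e-44, exact McNemar test), and CACGTG, the E-box of MYC, USF and the clock factors, at 5.41% against 1.78% (341 against 112 peaks, adjusted p = 2.41e-27). ETS sites (1.41% against 0.365%), YY1 sites (32 against 4 peaks), NRF1 sites (23 against 5) and CRE palindromes, bound by CREB and ATF proteins (54 against 20, exact test, adjusted p = 2.88e-04), were also enriched. The GC box was not particular to promoters: it was at 1.34% of distal summits against 0.395% of their control windows (ratio 3.35, exact test, adjusted p = 6.29e-10). FOXA sites (27 against 62, exact test, adjusted p = 7.17e-04), GATA sites (14 against 51, adjusted p = 1.51e-05), nuclear receptor monomer sites (11 against 57, adjusted p = 6.89e-08) and the NFIL3-type site (14 against 33, adjusted p = 0.0165) were less common at promoter summits than 500 bp away. The GATA site was listed as a control, so windows 500 bp away were not a neutral comparison for promoter summits. This also limits the promoter enrichments above. Against summit windows shuffled to keep their dinucleotides, FOXA and NFIL3-type sites were instead more common than in the comparison (ratios 2.62 and 4.14). GATA sites (ratio 0.935, exact test, adjusted p = 1) and nuclear receptor monomer sites (ratio 1.21) were not past the threshold there. Among the peaks of higher fold NRF1 (ratio 5.67 against 4.27 with all peaks; adjusted p = 0.0879), FOXA (0.579 against 0.440; 0.162) and NFIL3-type sites (0.419 against 0.433; 0.151) were not past the threshold in exact McNemar tests. With 25 bp either side NRF1 (ratio 3.80; adjusted p = 0.136) and NFIL3-type sites (0.484; 0.241) were not past it either in exact tests. The UPRE core, bound by XBP1, was at 43 summits against 36 control windows (exact test, adjusted p = 0.614), and the ERSE, bound by ATF6 with NF-Y, was at 0 summits against 2 control windows (adjusted p = 0.614).

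**Figure D2:**
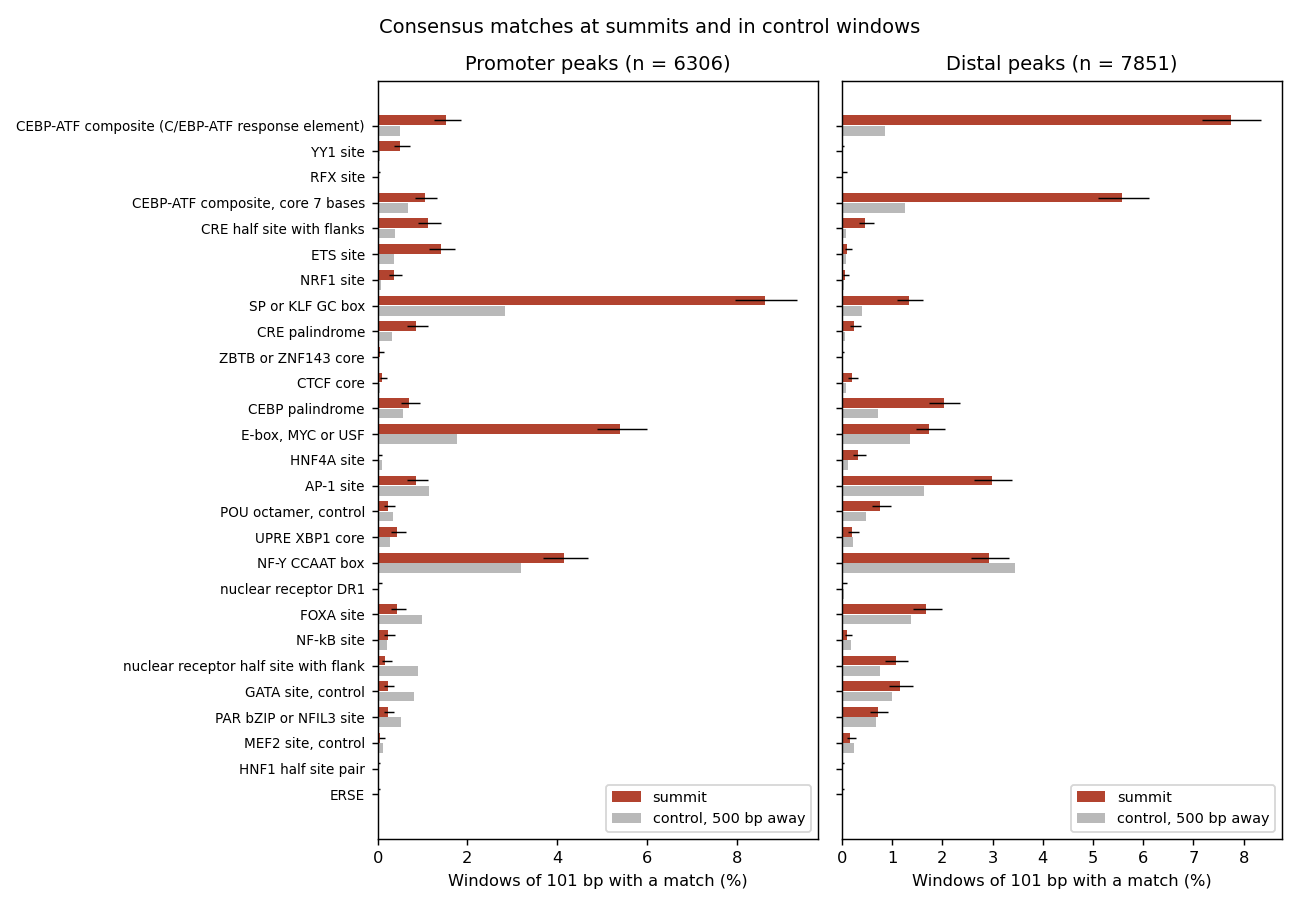
Percent of windows with a consensus match within 50 bp of peak summits (red, with 95% Wilson intervals) and in control windows 500 bp away (grey), for 6306 promoter and 7851 distal peaks. The composite element leads among distal peaks (7.74% against 0.853%) and the GC box among promoter peaks (8.63% against 2.84%).

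**Figure D3:**
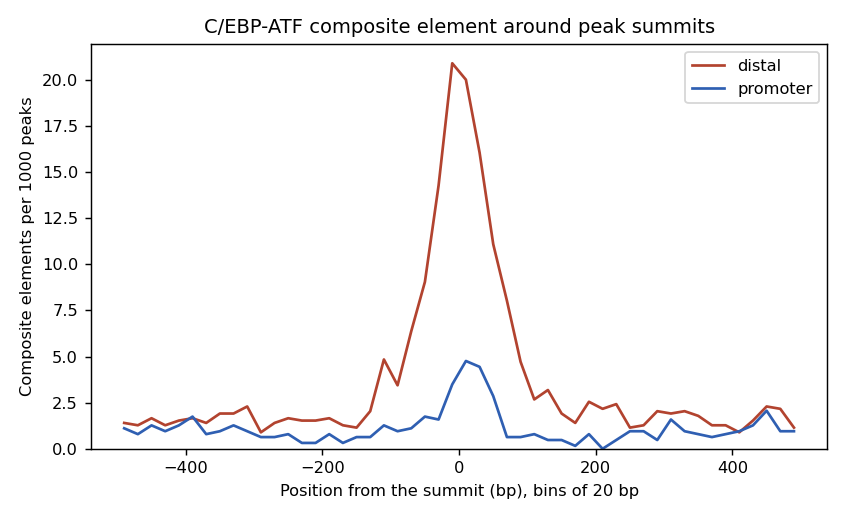
Number of composite elements per 1000 peaks in bins of 20 bp, by position from the summit in bp, for distal (red) and promoter (blue) peaks. Elements gather at the summit in both classes, and the distal curve is the higher.

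Peaks with a C/EBP-ATF element, and with some other motifs, were also stronger. At promoters, the median authors' fold was 10.5 in the 96 peaks with the composite element and 6.62 in the others, a difference in mean log2 fold of 0.70 (permutation test with 100000 resamples, two-sided, p = 1e-05, the smallest it can give, adjusted p = 8.00e-05). The CRE palindrome went with a difference of 0.32 (54 peaks, permutation test, adjusted p = 0.00456) and the C/EBP palindrome with 0.31 (44 peaks, adjusted p = 0.0121; 0.0880 with −log10 q in place of fold). The E-box went with 0.49: 341 promoter peaks with it had a median fold of 9.74 against 6.56 (permutation test, adjusted p = 8.00e-05). The octamer of POU factors, listed as a control, went with a difference of 0.57 in 15 peaks (permutation test, adjusted p = 0.0114), and in the 12 of these without a composite element the difference was 0.66 (p = 0.00205). At distal peaks the composite element went with a smaller difference of 0.19 (608 peaks, median 8.25 against 6.75, permutation test, adjusted p = 1.15e-04), and the C/EBP palindrome with 0.20 (159 peaks, adjusted p = 0.0128). The largest distal difference that passed was 0.28, for the nuclear receptor monomer site (84 peaks, permutation test, adjusted p = 0.0128). In all, 7 of 24 motifs that could be tested went with higher fold at promoters and 4 of 23 at distal peaks.

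Promoter and distal peaks had nearly equal folds. The median was 6.65 at promoters and 6.75 at distal sites, and the mean log2 fold at promoters minus that at distal sites was -0.10 (SD across peaks 0.69 and 0.81; permutation test, two-sided, p = 1e-05, the smallest it can give). In mean log2 of −log10 q the difference was 0.02 (permutation p = 0.343). In mean log2 fold it was -0.03 without the peaks that match a primate repeat (permutation p = 0.0289). Without the compact class described next, whose definition by high fold favours such a change, it was 0.01 (permutation p = 0.268).

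The distal peaks of highest fold had a narrow range of widths. Of the 5 highest, 4 lay in sequence annotated as intron, with the nearest protein-coding start sites those of Ptn (158.2-fold, chromosome 6, 36899314 to 36899627), Hapln1 (139-fold, chromosome 13, 89570495 to 89570800), Ybx3 (132-fold, chromosome 6, 131377407 to 131377723) and Fut8 (130-fold, chromosome 12, 77261432 to 77261751), and 1 in intergenic sequence 463021 bp from the start site of Slc35b3 (149-fold, chromosome 13, 39423740 to 39424056). All 5 were 306 to 320 bp wide, none held a C/EBP or ATF match within 50 bp of the summit, and 3 of the 5 summit windows matched a primate repeat better than its rodent counterpart. In all, 393 distal peaks were 290 to 340 bp wide with a fold of at least 20, limits chosen after the peaks were seen. The composite element was at 8 of these 393 (2.04%) and at 35 of the 184 other distal peaks of that fold (19.0%, Fisher's exact test, two-sided, p = 4.54e-12).

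**Figure D4:**
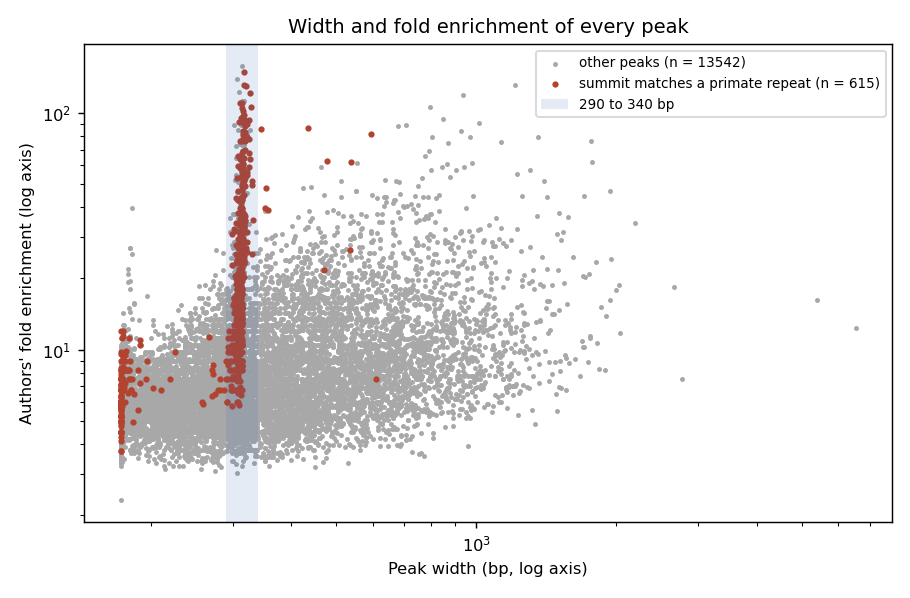
Authors' fold enrichment (log axis) against peak width in bp (log axis) for every peak. Red points are the 615 peaks whose summit window matches a primate repeat, grey points are the 13542 others, and the shaded band marks 290 to 340 bp, where red points stack up to the highest folds.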

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

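The tests in this part were chosen after the compact peaks had been seen.

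Signal outside the planned comparisons appeared in the sequence under the summits. In 584 of 14157 summit windows the sequence matched a primate SINE better than its rodent counterpart, against 4 of the control windows 500 bp away. The rodent counterpart was the better match in 527 summit windows against 352 control windows. It was raised at distal summits (503 against 227) and not at promoter summits (24 against 125). Of the 584 peaks that matched the primate SINE, 564 were distal and 20 were at promoters. Another 31 summit windows, against 0 control windows, held 5 or more units of a primate satellite pentamer, none of which is among the 584.

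The pattern was strongest in the compact distal peaks, 393 peaks 290 to 340 bp wide with a fold of at least 20. Among them 42.2% of summit windows (Wilson interval 37.5 to 47.2%) matched the primate repeat and 0 of the control windows did, as DNA of another species in the immunoprecipitate would give. The control windows lie outside these peaks, so a short mouse repeat under the summit could leave them blank too. Their count therefore does not favour DNA of another species. The rodent counterpart was matched more often too, at 56 of these summits against 15 control windows. Copy number or collapsed repeats of the mouse genome would raise the input too. The background of these peaks was compared with the genome-wide value but not kept as a test, since a class chosen by fold over background leaves out peaks where it is raised, so this point stays open. The composite element was at 2.04% of the compact summits, against 19.0% of the other distal peaks with a fold of at least 20. The width limits that separate these groups were chosen after the peaks were seen, and most of the other peaks lacked the element too. Its low share therefore cannot tell whether CHOP was bound at the compact peaks, and this point stays open. Primate DNA in the immunoprecipitated library is an untested candidate source of the compact peaks. The aligned windows were of the mouse reference sequence, and no read was examined. The origin of such DNA, the part of mouse repeats, and the source of the compact peaks without a match stay open.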

How the results depend on the processing

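The removal of compact peaks and of repeat-matching peaks was chosen after seeing the data; the other alternatives were fixed beforehand. The promoter share stayed between 39.4% (500 bp) and 51.0% (without the top 1% by score and repeat-masked peaks), above its genome share each time. The counts of lists with a higher rate (9 to 18), of motifs enriched at all summits (10 to 15) and of chromosomes departing from length (15) stayed within 1.5 times of the values reported. Lists with a lower rate numbered 3, against 0 among the peaks of higher fold, 5 with the nearest start site only and 1 with composition as covariate. Motifs enriched at promoters numbered 9, against 15 with shuffled windows. Promoter minus distal log2 fold turned from -0.10 to 0.0125 without compact peaks, an outcome that their definition by high fold and their place (393 of 410 distal) favour. Without repeat-matching peaks it was -0.03. With −log10 q in place of fold the difference, in log2 of −log10 q, was 0.0208. Promoter peaks had a median background of 1.12 reads and a median of 13 reads at the summit, against 0.357 and 9 at distal peaks. Whether this gives the change with −log10 q was not tested.

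Odds ratios crossed 1 for lists that had not passed Fisher's test. Those of the Fisher tests carry 0.5 added to each count, which matters near 1. Those with composition come from the logistic regression, without that addition and adjusted for the covariates. Acute-phase proteins rose above 1 with −log10 q of at least 5 (1.34), a fold of at least 5 (1.16), higher fold (1.16), 3 kb (1.9), the nearest start site (1.04), the outermost start site (1.04), any peak within 50 kb (3.96) and composition (6.52). Complement and coagulation, above 1 (1.02) only through the added 0.5 since 27.3% is below the 27.9% of other genes, was below 1 with −log10 q of at least 5 (0.916), without top-score and repeat-masked peaks (0.826), without compact or repeat-matching peaks (0.814 for both), at 500 bp (0.516) and the outermost start site (0.71). Urea cycle genes fell to 0.958 at 500 bp and 0.751 at the outermost start site. P450 genes rose to 1.35 with any peak within 50 kb and 3.34 with composition. With composition, lipoprotein assembly rose to 1.06 and ribosomal proteins (0.891), cholesterol synthesis (0.935), cell cycle (0.591) and oxidative phosphorylation (0.684) fell below 1. With shuffled windows, NFIL3-type (4.14), FOXA (2.62) and nuclear receptor monomer sites (1.21) at promoters turned from depleted to enriched ratios. The cause of these changes was not tested. No paired analysis was possible because each group has 1 library. Depth limits most the 6489 peaks on 10 or fewer reads.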

Other observations

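The tests in the first 2 paragraphs were chosen after the results were seen, and those on the E-box were written beforehand. Tests on promoter peaks in the last paragraph were chosen after the results were seen, except the differences in fold by motif, which come from a planned test.

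Peaks with the C/EBP-ATF composite element were near genes of 10 of the 33 lists more often than near other genes. Counting any peak within 50 kb, 18 lists passed. Genes near peaks without the element were not the comparison, so the test cannot tell the element from peaks in general. The integrated stress response list was also made of known CHOP or ATF4 targets. Of 704 such peaks, 523 lay within 50 kb of their nearest protein-coding start site and named 496 genes. Integrated stress response genes were the nearest gene of such a peak in 11 of 24 cases (45.8%, Fisher's exact test, adjusted p = 4.63e-11 over 33 lists), aminoacyl-tRNA synthetases in 9 of 20 (adjusted p = 3.28e-09) and serine and one-carbon genes in 6 of 17 (adjusted p = 1.45e-05), against 2.22% of protein-coding genes outside the stress list. Secreted plasma proteins followed with 5 of 20 (Fisher adjusted p = 5.68e-04), among them Ahsg (21-fold, 9671 bp away) and Itih1 (21-fold, 1219 bp away), and cholesterol synthesis with 4 of 20 (adjusted p = 0.00627). Translation initiation (adjusted p = 0.0125), ER chaperones, acute-phase proteins and the circadian clock (0.0364 each) and immediate early genes (0.0484) also passed Fisher's exact test. Genes outside the naming rule and chosen after their values were seen include Sesn2, an inhibitor of mTORC1 signalling (26.8-fold, 3595 bp away), Cdkn1a, the cell cycle inhibitor p21 (36.2-fold, chromosome 17, 29078838 to 29079250, 11929 bp away), and Klf9 (23.6-fold, 6205 bp away).

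Promoter CpG content and gene families separated genes with a promoter peak from those without. The share of genes with a promoter peak rose from 1.19% in the lowest of 5 equal groups by promoter CpG ratio to 63.0% in the highest. Of 111 families of at least 20 genes sharing a symbol stem, 21 had a higher and 30 a lower rate than other genes, and 2 and 6 with base composition as covariate (Fisher's exact test and likelihood-ratio test, adjusted). Zbtb genes, which encode zinc finger repressors, had 29 of 41 (Fisher adjusted p = 2.74e-07; 0.0342 with composition), while mitochondrial ribosomal Mrpl genes had 9 of 49 (adjusted p = 0.243; 0.00296 with composition, below prediction). Chromosome M carried 3 peaks with folds of 12.4 to 16.2 over a background of 13.0 to 22.6 reads, against a median background of 0.594 over all peaks.

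The E-box at promoter summits and its higher fold were weighed against base composition and neighbouring elements. Real summit windows held it 2.60 times as often as dinucleotide-shuffled ones (5.41% against 2.08%, exact McNemar test, p = 9.87e-24), which argues against composition alone. Without windows that hold a C/EBP, ATF, AP-1 or NFIL3-type element the difference in mean log2 fold was 0.51 (321 peaks with the E-box, permutation p = 1e-05, the smallest it can give), and within 5 groups of equal size by window GC content it was 0.49 (permutation p = 1e-05, the smallest it can give). None of these explanations removed the pattern, and no biological explanation was tested.

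Most promoter peaks had no exact match to a C/EBP-type consensus within 50 bp of the summit, and part of this can be weighed. Distal summits often lacked a match too: the most frequent such element there, the composite, was at 7.74% of them. It was rarer at promoter summits (1.52%), as were the C/EBP palindrome (0.698% against 2.03% of distal summits) and the AP-1 site (0.856% against 2.98%). The CRE palindrome was more common at promoter summits (0.856% against 0.242%). The share of distal peaks with any such element was not computed. Base composition alone does not account for which promoters had peaks: 2 of 61 off-tissue genes had a promoter peak where their GC and CpG content predicts 7.76 (one-sided exact test, p = 0.00625). Among these lists it rests on the neuronal one, with 0 of 20 against 5.24 predicted, while muscle genes met their prediction (2 of 22 against 2.26) and the 19 olfactory receptors were too few to depart from theirs (0 against 0.260). The whole family of olfactory receptors, with 2 of 1134, was below its prediction (likelihood-ratio test, n = 21866 genes, adjusted p = 1.98e-04). For the 96 promoter peaks with the composite element, a comparison of fold with all other promoter peaks and another with octamer peaks were tried against a general signal of open promoters. The first comparison was planned, but its use against such a signal and the comparison with octamer peaks were chosen after the folds were seen. Neither was kept as a test of that signal, since the control motifs also differ among themselves (0.57 for the octamer, -0.10 for GATA and -0.05 for MEF2 in mean log2 fold against other promoter peaks), so this point stays open. For the 6023 promoter peaks (95.5%) without an exact match to a C/EBP, ATF, AP-1 or NFIL3-type element within 50 bp, CHOP held by other factors and such a general signal cannot be told apart, since no other antibody or CHOP-deficient liver was analysed here.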
